A study of Mus musculus with 6 samples.

How the data were processed

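RNA was sequenced from primary peritubular myoid cells of C57BL/6J mice, 3 libraries without treatment and 3 with 50 nM ET-1 for 5 min. Groups and replicate numbers were taken from the sample labels. The labels do not say whether the libraries of a group came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical.

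Per the labels, libraries were made from total RNA with the BGI protocol. Per the submitters' processing notes, the tools were HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 and the build mm10, with no role given for each. The authors deposited 1 table of genes with an FPKM value per library rounded to 2 decimals, which is called RPKM in the series' file and FPKM per the file headers. The table also holds the authors' mean FPKM per group, the authors' log2 fold change, and the authors' p-value and q-value per gene, the q-value being named for DEGseq per the file headers. The sign of the authors' log2 value was that of ET-1 minus untreated mean FPKM in 99.5% of genes. How the authors' comparison treated replicates is not given in the sources used here. The table's text columns of pathway annotation and co-expression modules were deposited by the authors, and the modules were not used here.

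Of 22135 rows, 19285 had values in the 6 libraries. Gene symbols stored as dates in 27 rows were restored from the gene identifier with a RefSeq table of assembly GRCm38.p6, in which 19226 identifiers were found. No gene of the mitochondrial chromosome had a value, so the list of mitochondrially encoded genes was not tested. Coordinates are those of the deposited table in mm10.

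Read counts were not used. Low FPKM values of genes 300 to 1200 bases long (FPKM 0.05 to 0.6) lay near whole multiples of 1 fragment, with 87.6% to 92.6% within 0.15 of a whole number, which gave 18040000, 17920000 and 17910000 fragments for the untreated and 17580000, 17370000 and 17850000 for the ET-1 libraries. Because RSEM values need not be whole fragments, no count test was run. At this depth a gene near 1 FPKM rests on few fragments, and its value is less precise than that of an abundant gene.

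Genes with an FPKM of at least 1 in at least 3 libraries (11664 genes) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, group as the only term, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. An exact permutation test of 3 against 3 libraries could not go below p = 0.1 for a single gene, so none is given. Gene lists with at least 5 tested members (24 of 27 written) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move one way on balance. Replication-dependent histones had 4 tested members, erythroid markers 0 and mitochondrially encoded genes 0. Across the lists 3 genes stood in more than 1.

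The design, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule named Edn1, Ednra and Ednrb, the 10 largest changes in each direction among genes past the threshold whose groups do not overlap and whose higher group had a mean FPKM of at least 1 (predicted genes left out), up to 2 passing members per direction of each list or else the member with the smallest p, and Fos, Egr1, Ier2, Nr4a1, Acta2, Myh11 and Cnn1. Other genes in the text were chosen after their values were seen. The results of 1 gene and 1 gene list are not reported here.

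Same-numbered libraries deviated together from their group means, with correlations across genes of 0.228, 0.523 and 0.202 for numbers 1, 2 and 3. All lie above 0.1, so the replicate number was also used as a block, although the labels say nothing about what a number stands for. Only 2 of the 6 libraries correlated best with their own number. Untreated library 3 with ET-1 library 1 (0.271) and untreated library 1 with ET-1 library 3 (0.2495) lay above the same-number values of libraries 1 and 3. The deviations of a group's libraries cancel out, so the match of the libraries numbered 2 raises the correlations among numbers 1 and 3. These correlations therefore do not show that numbers 1 and 3 pair. The block fit left 2 residual degrees of freedom per gene. Untreated libraries 1 and 3 had a Pearson correlation of 0.996 on log2(FPKM + 1), against 0.973 to 0.984 for the other pairs within a group. Their fragments still differed by more than sampling noise, which speaks only against 1 library deposited as both. They were counted as 2 samples, although whether they are independent is not known. A fit with their mean as 1 library was added after the data were examined.

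Data were simulated with the spread of these libraries (11664 genes, 200 changed, 5 simulations). The limma step recovered 11.0% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 94.5% of those changed 4-fold. False calls were 6.6 among 119.4 on average. Genes and libraries were drawn independently there, which these data do not follow, so the share of false calls need not hold for them. In 40 simulations of lists of 20 genes, unchanged lists whose members share variation passed the unadjusted threshold in 57.5% with a preset correlation and in 0% with an estimated one, so the calls made with a preset correlation are given with both.

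Alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, equal library medians, quantile normalization, limma without the trend, the replicate block, thresholds of 0.1 and of 2-fold, Spearman against Pearson correlation, and leaving out each library in turn. Removal of a loess trend on transcript length was added after the data were examined, as was the count of list members with an untreated library within the range of the ET-1 libraries. Pathway enrichment, also added then, used Fisher's exact test (one-sided) on the deposited pathway annotation with Python 3.11.15 and scipy 1.17.1, over 5918 annotated tested genes and pathways of 10 to 500 tested members. Fragments were compared between libraries by chi-square over genes with 1 transcript and 100 to 5000 fragments in a pair.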

Results

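Primary cultures of testicular peritubular myoid cells from C57BL/6J mice were profiled by RNA sequencing. These smooth-muscle-like cells wrap the seminiferous tubules of the testis and contract them. Endothelin-1 (ET-1) is a peptide that contracts smooth muscle through the endothelin receptors A and B. Total RNA came from 3 untreated libraries and from 3 libraries of cells given 50 nM ET-1 for 5 min. Gene expression was given as FPKM (fragments per kilobase of transcript, scaled to the depth of the library) for 19285 genes. The size of the steps between low FPKM values put the depth at 17370000 to 18040000 fragments per library, and 16078 to 16537 genes were above 0 in each. The comparison asks which transcripts differ between cultures of peritubular myoid cells with and without a short exposure to ET-1. The Leydig cell gene Insl3 had the highest FPKM of untreated library 3 (4532 FPKM), so a change need not be one of myoid cells.

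Genes of the interferon response were far lower in the ET-1 libraries, and the type I collagen genes were higher. Ifit1, an interferon-induced antiviral gene, went from 77.4 ± 49.0 FPKM in untreated cells to 4.83 ± 1.36 after ET-1 (mean ± SD, n = 3 each), and Isg15, a ubiquitin-like protein induced by interferon, from 557.1 ± 279.7 to 73.0 ± 36.0 FPKM. Col1a1 and Col1a2, the chains of type I collagen, were 2.15-fold and 2.21-fold higher by the ratio of mean FPKM. Thy1, a surface glycoprotein of fibroblasts, rose from 2.25 ± 0.20 to 13.95 ± 1.77 FPKM (n = 3 each). Of 11664 genes tested with limma, 404 passed a Benjamini-Hochberg adjusted p of 0.05, 183 of them higher and 221 lower after ET-1. The values of the groups were fully separated in all 404 genes, and in 3602 tested genes altogether (30.9%). Chance gives 10% on average over all groupings into 3 and 3. Genes vary together, so the share in 1 grouping can lie well off that average. Blocking on the replicate number gave 1102 genes, 497 higher and 605 lower, among them all 404. Whether the numbers 1 and 3 pair libraries of the groups is not known. The calls rest on single libraries: 0 genes passed in limma without untreated library 3 (1653 at an unadjusted p under 0.05), 79 without untreated library 1, 297 (96 higher) without untreated library 2, and 75, 105 and 797 without ET-1 libraries 1, 2 and 3. With untreated libraries 1 and 3, the closest pair, averaged as 1 library, 0 genes passed in limma (1766 at an unadjusted p under 0.05).

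**Figure D1:**
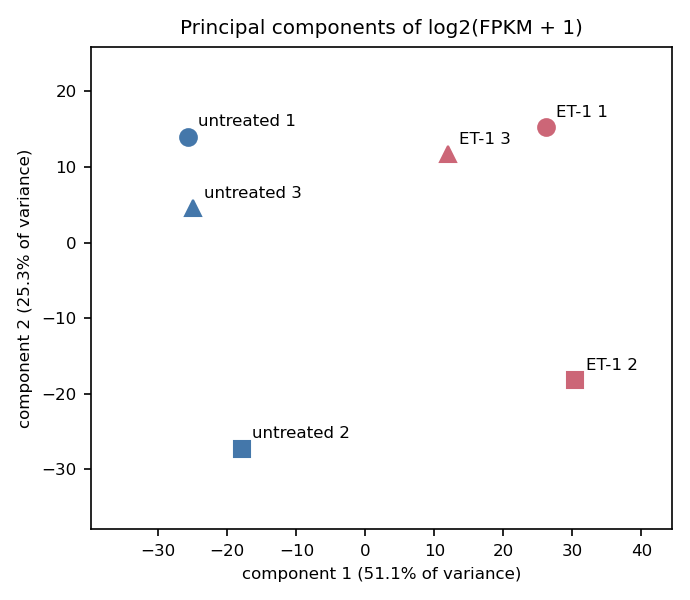
Principal components of the log2(FPKM + 1) values of the 11664 tested genes, with 1 point per library (blue, untreated; red, ET-1; marker shape, replicate number). Component 1 (51.1% of the variance) has the untreated libraries between -25.7 and -17.9 and the ET-1 libraries between 12.01 and 30.4, and component 2 (25.3%) sets the libraries numbered 2 of both groups apart from the rest.

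Neither the gene of ET-1 nor those of its receptors passed the limma test. Edn1, the gene of ET-1 (chromosome 13, 42301476 to 42307990, mm10), was at 67.2 ± 30.1 FPKM in untreated cells and 38.7 ± 25.6 after ET-1 (n = 3 each; limma adjusted p = 0.348). Ednra, the endothelin A receptor (chromosome 8, 77663029 to 77724452), was at 3.96 ± 0.97 and 3.93 ± 1.68 FPKM (n = 3 each). Ednrb, the endothelin B receptor (chromosome 14, 103814615 to 103844476), was at 1.30 ± 0.13 and 0.96 ± 0.61 FPKM (n = 3 each). Of the 25 tested endothelin signalling components, 1 rose and 1 fell, and adjusted over the list alone 3 rose and 2 fell (3 and 1 over all genes with the replicate block). Mapk3, which encodes the kinase ERK1, rose from 89.6 ± 1.1 to 143.4 ± 12.5 FPKM (n = 3 each; limma adjusted p = 0.0254). Rgs5, an inhibitor of G protein signalling, fell from 3.12 ± 0.47 to 1.28 ± 0.37 FPKM (n = 3 each; limma adjusted p = 0.0428). The list's median log2 change of -0.034 and mean of -0.018 lay below 0, whereas camera, a test of a gene list against all other genes, gave the direction up with an adjusted p of 0.778. In fry, the test of change in either direction gave this list an adjusted p of 0.00522, which does not compare it with other genes.

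Of the 28 tested immediate early response genes, 1 rose and none fell, and adjusted over the list alone 3 rose and 2 fell. By sign 15 were higher and 13 lower, with a median log2 change of 0.031 (preset camera adjusted p = 0.778). The members that fell over the list alone were Ier3 and Klf6. Ier3 was at 329.3 ± 34.1 and 190.3 ± 40.5 FPKM (limma adjusted p = 0.0290 over the list alone). Klf6 was at 75.5 ± 4.4 and 51.8 ± 10.0 FPKM (0.0433; n = 3 each). Over all genes with the replicate block 3 rose and 3 fell, and in fry the test of change in either direction gave an adjusted p of 0.00754. Fosb, a subunit of the transcription factor AP-1, rose from 3.35 ± 0.12 to 10.4 ± 2.8 FPKM (n = 3 each; limma adjusted p = 0.0249). Egr1, an early growth response factor, was at 38.8 ± 8.4 and 80.1 ± 28.8 FPKM (n = 3 each; adjusted p = 0.0887 over all genes, and 0.0433 over the list alone). Ier2 was at 68.8 ± 5.2 and 102.2 ± 13.6 FPKM (adjusted p = 0.0626), and Fos at 27.6 ± 4.4 and 49.1 ± 17.3 FPKM (adjusted p = 0.137; n = 3 each, limma). With the replicate block, Egr1 (adjusted p = 0.0296) and Ier2 (adjusted p = 0.0279) passed the limma test and Fos (adjusted p = 0.0741) did not. Nr4a1 was at 20.5 ± 3.9 and 38.8 ± 33.3 FPKM (n = 3 each), with 76.6 FPKM in ET-1 library 3 and 13.5 in ET-1 library 1.

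None of the 17 tested smooth muscle contractile genes passed the limma test on its own. Acta2, the smooth muscle actin, was at 1605 ± 115 and 1841 ± 345 FPKM, Cnn1, the actin-binding calponin 1, at 65.8 ± 5.0 and 111.1 ± 47.2 FPKM, and Myh11, the smooth muscle myosin heavy chain, at 48.5 ± 4.5 and 33.7 ± 13.4 FPKM (n = 3 each). Cald1, which encodes the actin-binding caldesmon, had the smallest p of the list (353.7 ± 22.4 and 505.8 ± 72.8 FPKM, n = 3 each; limma adjusted p = 0.0879). As a list the contractile genes passed camera with a preset correlation (median log2 change 0.18, adjusted p = 0.0319). That call was lost with an estimated correlation (adjusted p = 0.878), without ET-1 library 2 (median 0.026, adjusted p = 0.665) and without untreated library 2 (0.146, adjusted p = 0.147). It was also lost with quantile normalization (median 0.178, adjusted p = 0.136), with equal medians (0.226, adjusted p = 0.0564) and without a filter (0.139, adjusted p = 0.344). No gene passed limma among 17 genes of calcium handling and 15 peritubular and mesenchymal receptors and regulators. Their members with the smallest p were Atp2a2 (log2 change -0.51 ± 0.14, SE) and P2rx4 (-0.39 ± 0.09). For the receptors and regulators, the median of -0.042 and the mean of -0.022 lay below 0, with the direction up in camera and down in fry.

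Of 37 tested extracellular matrix and basement membrane genes, 5 rose and none fell, and adjusted over the list alone 7 rose and 1 fell. Over all genes with the replicate block, 8 of these matrix genes rose and 5 fell. Col1a2 rose from 203.2 ± 6.6 to 448.0 ± 91.8 FPKM and Col1a1 from 203.6 ± 16.5 to 437.4 ± 110.2 FPKM (n = 3 each; limma adjusted p = 0.0250 and 0.0375). The other members that rose were Col5a2, Lama2 and Bgn. Col3a1, the chain of type III collagen, was at 163.9 ± 63.8 and 103.4 ± 42.7 FPKM, and Mmp2, a gelatinase, at 44.0 ± 25.2 and 12.2 ± 5.0 FPKM, and neither passed (n = 3 each). As a list, camera gave an adjusted p of 0.00721 with a preset correlation (median log2 change 0.28) and an adjusted p of 0.878 with an estimated correlation. The preset call of the matrix list was lost without untreated library 2 (median 0.202, adjusted p = 0.232) and without ET-1 library 3 (median 0.15, adjusted p = 0.0730). Among 20 cell adhesion and junction genes, Cdh11, a mesenchymal cadherin, rose from 7.14 ± 0.69 to 12.04 ± 1.74 FPKM (n = 3 each; limma adjusted p = 0.0475). Among 22 growth factors, Igf1 rose from 2.94 ± 0.62 to 7.98 ± 2.76 FPKM and Bmp2 fell from 6.15 ± 1.10 to 1.47 ± 0.99 FPKM (n = 3 each; limma adjusted p = 0.0498 and 0.0448). The Bmp2 call was lost at a pseudocount of 0.1 (adjusted p = 0.0690), and the Igf1 and Cdh11 calls at a pseudocount of 5 (adjusted p = 0.0646 and 0.0545). Without a filter the calls of Cdh11, Igf1 and Bmp2 were lost (limma adjusted p = 0.077, 0.087 and 0.080). With the replicate block, 1 adhesion gene rose and 2 fell, and 1 growth factor rose and 2 fell. The growth factors' median log2 change was 0.048 and their mean -0.016, with the direction up in camera and down in fry.

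The interferon response held the largest group of calls. Of 19 tested members, 12 fell and none rose, and adjusted over the list alone 18 fell, which leaves out Irf1 (16 fell over all genes with the replicate block). Over all genes 7, 6 and 9 members passed without ET-1 library 1, 2 and 3, and 12 without untreated library 1 or 2. The count was 0 without untreated library 3 and with untreated libraries 1 and 3 averaged. The median log2 change was -2.26, and all 19 members were lower. Besides Ifit1 and Isg15, the members that fell include Irf9 and Stat2, subunits of the transcription factor that carries the interferon signal. Irf9 went from 38.6 ± 2.9 to 11.7 ± 0.9 FPKM (n = 3 each; limma adjusted p = 0.00664). Usp18, a protease that removes Isg15 from proteins, went from 129.3 ± 67.6 to 12.1 ± 0.6 FPKM (n = 3 each; limma adjusted p = 0.0146). The adjusted p in camera was 7.24e-15 with a preset correlation, 0.878 with an estimated correlation of 0.705, and 0.0661 in fry. Untreated library 2 had the highest level of all 19 genes, with 263.8 FPKM of Ifit3 against 43.1 and 91.9 in untreated libraries 1 and 3 and 5.45 to 8.74 in the ET-1 libraries.

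The 10 genes with the largest falls were Cxcl5, Ifit3, Ifit1, Ifi44, Rtp4, Ifit3b, Zbp1, Usp18, Iigp1 and Apol9a, with log2 changes from -4.24 to -3.09. Cxcl5, a neutrophil chemokine, was at 50.9, 9.29 and 56.5 FPKM in the untreated libraries and at 1.90, 0.17 and 0.33 FPKM in the ET-1 libraries (limma adjusted p = 0.0344). It was the only member of the 17 tested cytokines and chemokines that passed, whereas 1 rose and 2 fell with the replicate block. The Cxcl5 call was lost at a pseudocount of 5 (limma adjusted p = 0.0532) and without a filter (0.0614). Ifit3 and Ifit3b, and Apol9a and Apol9b, are near-identical copies whose reads could have been divided between them, so each of these values is uncertain. Ifi44 (chromosome 3, 151730791 to 151749959) went from 62.0 ± 40.3 to 4.80 ± 2.45 FPKM, and Rtp4 (chromosome 16, 23609919 to 23614222) from 70.3 ± 16.0 to 6.53 ± 2.39 FPKM (n = 3 each; limma adjusted p = 0.0241 and 0.00837).

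The 10 genes with the largest rises were Mmp12, Scd4, S100a4, Aard, Thy1, Gstm6, Lyz2, Mageb16, Hist2h2ac and Dusp15, with log2 changes from 1.94 to 2.55. Mmp12, the macrophage metalloelastase, went from 6.11 ± 4.22 to 38.5 ± 17.7 FPKM, and S100a4, a calcium-binding protein of fibroblasts and macrophages, from 46.2 ± 12.1 to 220.2 ± 58.9 FPKM (n = 3 each; limma adjusted p = 0.0425 and 0.0173). Scd4, a stearoyl-CoA desaturase, went from 0.74 ± 0.17 to 8.48 ± 3.02 FPKM, and Mageb16 from 0.25 ± 0.18 to 3.99 ± 0.80 FPKM (n = 3 each). At such low values the log2(FPKM + 1) scale understates the change. Hist2h2ac has near-identical histone copies, which leaves its value uncertain. Of the 4 tested replication-dependent histones, 1 rose, and 3 rose adjusted over the list alone.

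The median changes of markers of other testicular cell types had different signs. Of 15 tested macrophage markers, 1 rose, and 10 rose adjusted over the list alone (median log2 change 1.13). Lyz2, the lysozyme of macrophages, rose from 42.7 ± 12.9 to 199.6 ± 98.5 FPKM (n = 3 each; limma adjusted p = 0.0373), and Tyrobp was at 14.7 ± 6.3 and 64.7 ± 37.6 FPKM (n = 3 each; adjusted p = 0.0553). Of 7 tested endothelial markers, 4 fell, and 6 fell adjusted over the list alone (median log2 change -1.33). Egfl7, a protein that endothelial cells secrete, went from 15.8 ± 1.6 to 4.6 ± 0.29 FPKM and Esam, an endothelial adhesion molecule, from 19.95 ± 5.53 to 4.51 ± 2.45 FPKM (n = 3 each; limma adjusted p = 0.00700 and 0.0354). Cdh5, the cadherin of endothelial cells, did not pass and was at 15.9 ± 5.5 and 19.4 ± 7.2 FPKM (n = 3 each). Of 12 tested Sertoli cell markers, Aard and Gstm6 rose, and 4 rose adjusted over the list alone (median log2 change 0.68). None of the 7 tested Leydig cell markers passed over all genes, and adjusted over the list alone 1 rose and 2 fell. Insl3, the peptide hormone of Leydig cells, was at 3647 ± 1394 and 1338 ± 742 FPKM (n = 3 each; adjusted p = 0.129), with 2040 FPKM in untreated library 2 and 2096 in ET-1 library 3, and Star, which carries cholesterol into mitochondria, at 73.1 ± 9.7 and 129.7 ± 25.7 FPKM (n = 3 each; adjusted p = 0.0562, and 0.0463 with the replicate block). None of the 8 tested germ cell markers passed. Untreated library 2 lay within the range of the ET-1 libraries in 7 of 12 Sertoli, 6 of 15 macrophage, 5 of 7 Leydig and 0 of 7 endothelial markers, against 0 to 2 markers of each list for untreated libraries 1 and 3. With the replicate block, 7 macrophage markers rose and 1 fell, 6 endothelial markers fell, 6 Sertoli markers rose, and 1 Leydig marker rose and 3 fell. The camera calls with a preset correlation for the macrophage (adjusted p = 3.251e-06), endothelial (4.227e-05) and Sertoli lists (0.00826) all had an adjusted p of 0.878 with an estimated correlation.

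**Figure D2:**
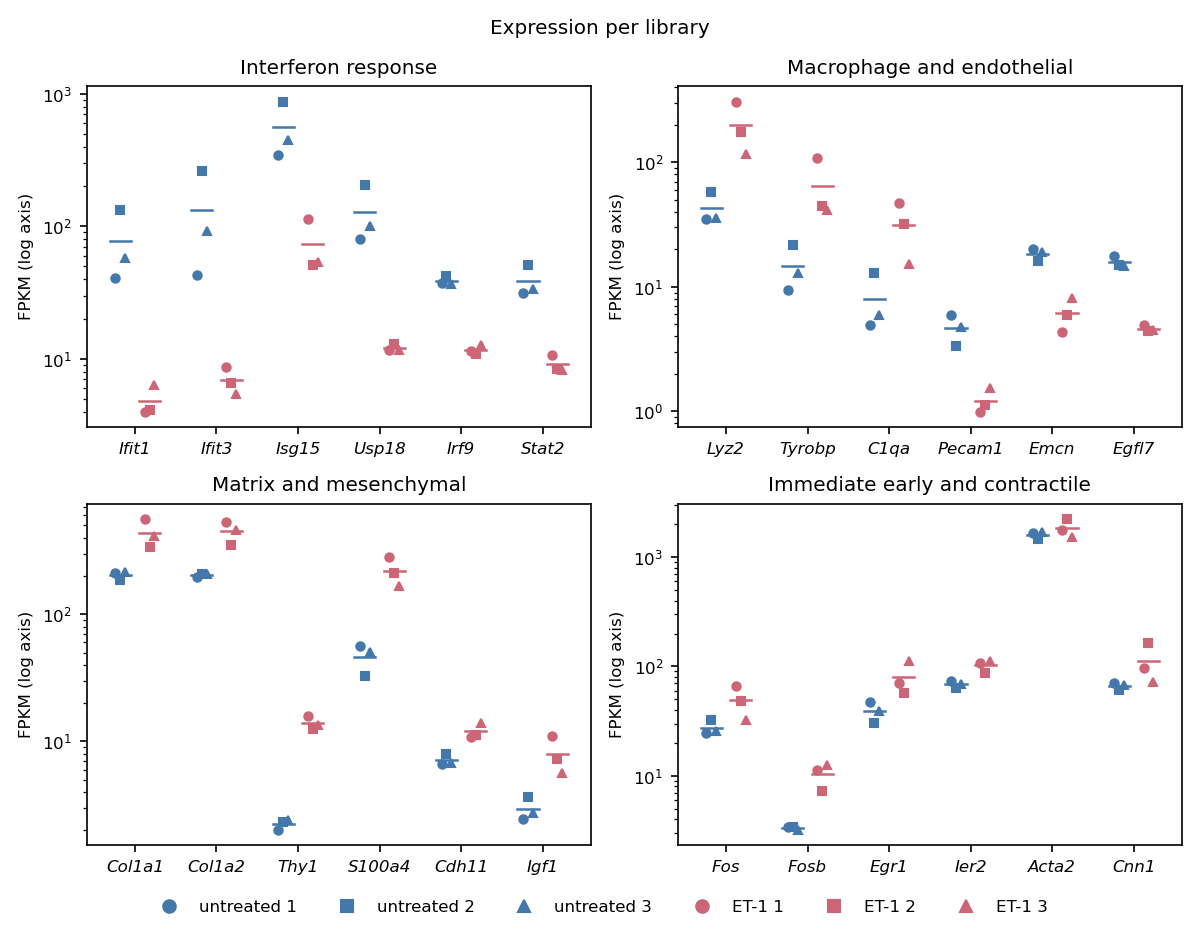
FPKM per library on a log axis for 24 genes in 4 panels, with 1 point per library (blue, untreated; red, ET-1; marker shape, replicate number) and a bar at each group mean. Ifit1 lies at 40.9 to 133.1 FPKM in the untreated libraries and 3.99 to 6.40 in the ET-1 libraries, whereas the Acta2 values of the groups overlap.

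The other lists held few calls. Of 9 lists past camera with a preset correlation, the remaining ones were cholesterol synthesis (19 members, median log2 change -0.42, adjusted p = 0.00721), proliferation (23 members, -0.20, adjusted p = 0.0267) and cytosolic ribosomal proteins (39 members, 0.10, adjusted p = 0.0323). None of their members passed limma, and 1 proliferation member, the replication factor Mcm3, fell adjusted over the list alone. With an estimated correlation the adjusted p was 0.878 for cholesterol synthesis and proliferation and 0.913 for ribosomal proteins, whose median turned to -0.006 with quantile normalization. Sc5d, an enzyme of cholesterol synthesis, was at 75.1, 22.9 and 55.7 FPKM in untreated libraries 1 to 3 and at 19.0 ± 5.8 FPKM after ET-1 (n = 3). Untreated library 2 lay within the range of the ET-1 libraries in 13 of the 19 cholesterol synthesis genes, and untreated libraries 1 and 3 in 2 and 1. The preset camera call of cholesterol synthesis was lost without untreated library 1 (adjusted p = 0.0817), without ET-1 library 3 (0.139) and with untreated libraries 1 and 3 averaged (0.0567). That of proliferation was lost without ET-1 library 2 (median -0.049, adjusted p = 0.665), without untreated library 1 (-0.174, 0.126) or 3 (-0.127, 0.119), with these averaged (0.117) and with quantile normalization (0.0522). That of ribosomal proteins was lost without untreated library 2 (median 0.047, adjusted p = 0.358), with equal medians (0.0564), without a filter (0.134) and with the length trend removed (0.612). Without ET-1 library 1 it was lost too, and the ribosomal median turned to -0.041 (preset camera adjusted p = 0.689). Rpl7 was at 988 ± 72 and 785 ± 103 FPKM (n = 3 each). Of 14 heat shock response genes 1 fell, the mitochondrial chaperonin Hspd1, from 218.7 ± 7.5 to 138.0 ± 14.4 FPKM (n = 3 each; limma adjusted p = 0.0308). Of 21 hypoxia and glycolysis genes 1 rose, Ankrd37, from 2.15 ± 0.07 to 4.40 ± 0.73 FPKM (n = 3 each; limma adjusted p = 0.0375). No member passed among 16 YAP and TEAD target genes, 17 genes of the unfolded protein response and 27 nuclear-encoded respiratory chain genes, where the members with the smallest p were Tgfb2 (log2 change -0.85), Creld2 (-0.52) and Cox4i1 (0.31). With the replicate block, limma also passed Mcm3 (adjusted p = 0.0235), Sc5d (adjusted p = 0.0247), Tgfb2 (adjusted p = 0.0306) and Creld2 (adjusted p = 0.0311). In that fit 7 proliferation, 3 cholesterol synthesis, 3 YAP and TEAD target genes and 1 gene of the unfolded protein response fell, and of the hypoxia and glycolysis genes 1 rose and 1 fell. With the replicate block 11 lists passed the preset camera test, adding YAP and TEAD targets (adjusted p = 0.0412) and cytokines and chemokines (adjusted p = 0.0344), and 0 passed with an estimated correlation.

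**Figure D3:**
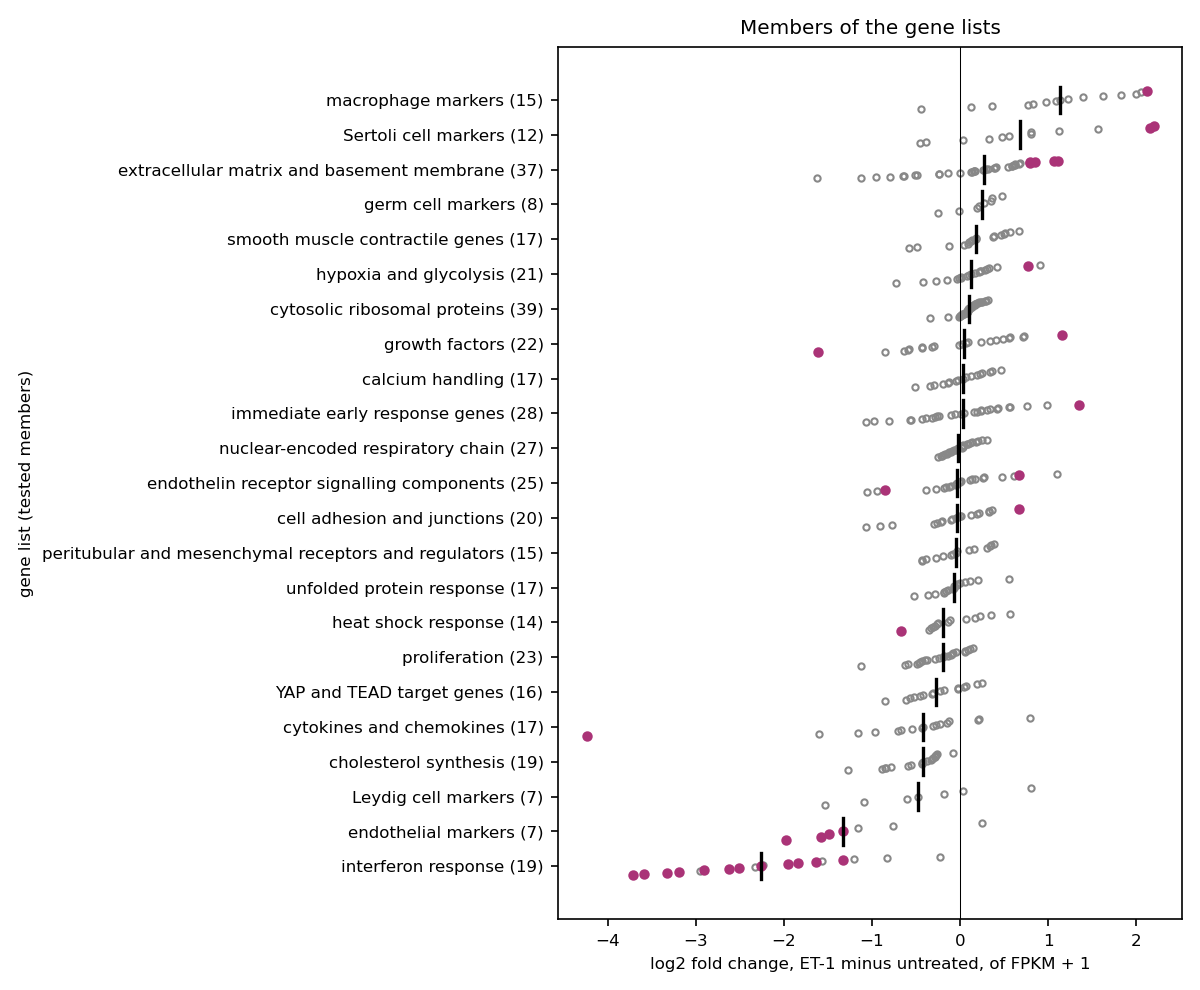
Log2 change of FPKM + 1 (ET-1 minus untreated) for each member of 23 tested gene lists, with tested members in parentheses. Filled points passed an adjusted p of 0.05 in limma, open points did not, and the black bar is the list's median, which runs from -2.26 for the interferon response to 1.13 for macrophage markers.

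The authors' deposited table also holds a comparison of the groups, with a q-value named for DEGseq. In the authors' deposited table, 11117 of 16812 genes had a q under 0.05, 5508 higher and 5609 lower after ET-1, and 1314 had a q of at most 0.001 with a log2 change of at least 1 in size. All 404 genes called here were among the calls of the authors' deposited table, in the same direction. Both comparisons used the same 6 libraries, and the authors' deposited table called 78.4% of the tested genes, so the overlap is no independent check. Of the 9146 tested genes with a q under 0.05 in the authors' deposited table, the 3 values per group overlapped in 60.9%. For Ifit1 the authors' deposited table gives a log2 change of -4.00, and for Thy1 2.63. Edn1, Fos, Egr1, Acta2 and Cnn1, which did not pass limma here, all had a q of at most 2.943e-155 in the authors' deposited table.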

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

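Averaging untreated libraries 1 and 3 and removing a length trend were chosen after seeing the data. All 404 genes kept their direction wherever they were tested. With fully separated groups this was fixed in advance, except where the scaling or the length trend was changed. The counts stayed within 1.5 times the main ones (404 genes, 183 higher, 221 lower) with pseudocounts of 0.1 and 5, equal medians, quantile normalization, no mean-variance trend and the length trend removed. The excess of lower genes turned round with equal medians (175 higher, 170 lower) and quantile normalization (164 and 158). It also turned round without ET-1 library 1 (42 and 33) or 2 (58 and 47). The other settings that called genes had more lower ones. Without a filter 193 genes passed (92 higher, 101 lower), with 17838 genes tested, and at a mean FPKM of at least 5 there were 118 higher. The replicate block gave 1102 genes (497 higher, 605 lower), and together with the length trend removed 1166 (582 and 584). Beyond the calls given with it in the report, it changed no call of a gene named by the rule. With untreated libraries 1 and 3 averaged, 0 passed in limma (0 higher, 0 lower; 1766 at an unadjusted p under 0.05). Leaving out 1 library gave 0 to 797 genes (0 to 322 higher, 0 to 475 lower), with 0 without untreated library 3 and 797 without ET-1 library 3. Of the named genes, Bmp2 lost its call at a pseudocount of 0.1, and Gstm6, Cxcl5, Ifit3b, Igf1 and Cdh11 at 5. Igf1 also lost it with equal medians, quantile normalization, no trend, the length trend removed and the mean of at least 5, and Zbp1 with quantile normalization. Without a filter Mmp12, Gstm6, Lyz2, Cxcl5, Ifit3, Ifit3b, Zbp1, Rgs5, Col1a1, Igf1, Bmp2, Cdh11, Ankrd37 and Esam lost it. Only the interferon, macrophage, endothelial and Sertoli lists kept the preset camera call wherever they were tested. A 2-fold minimum left 194 (79 and 115), and an adjusted p under 0.1 gave 1186 (520 and 666), by the construction of those thresholds. Of the 9 gene lists, 0 passed with an estimated correlation and 0 in fry for 1 direction. In either direction 9 lists passed fry, among them endothelin signalling and immediate early genes, which camera did not call. The median of the ribosomal proteins turned to -0.006 with quantile normalization and to -0.041 without ET-1 library 1, the lowest of -0.041 to 0.189 over the left-out libraries. The mean correlation within the ET-1 group was 0.969 by ranks. The cause of these shifts was not tested, apart from fewer libraries, more genes tested and the thresholds. Of the values for single genes and lists, 1101 stayed on their side of the threshold, 180 lost and 32 gained a call. A gene near 1 FPKM rests on few fragments at this depth.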

Other observations

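The pathway and cell type comparisons, the tests of explanations and the other splits of the libraries were chosen after the results were seen. By the deposited pathway annotation, 8 of 638 pathway tests passed (Fisher's exact test, Benjamini-Hochberg). That test takes genes as independent, whereas members of the interferon response list had an estimated correlation of 0.705, so its p-values are too small where members vary together. Among lower genes the strongest was Influenza A (18 of 157 tested members, 3.61 expected, adjusted p = 8.444e-06), with the interferon-induced Adar, Eif2ak2, Ifih1, Mx2, Oas2, Oas3, Pml and Trim25 but also Actg1 and Isoc1. Measles, Hepatitis C, Herpes simplex infection and NOD-like receptor signaling passed as well and all held Oas2 and Oas3, and Cytosolic DNA-sensing passed with Zbp1, Trex1 and Ifi204. Among higher genes the strongest was Protein digestion and absorption (8 of 61, adjusted p = 0.000645), through the collagens Col1a1, Col1a2, Col5a2, Col11a1, Col15a1, Col16a1 and Col27a1 and through Vit. The term Systemic lupus erythematosus (6 of 62, adjusted p = 0.0410) held the histone genes Hist1h2ai, Hist1h2bq, Hist1h2br, Hist2h2aa1 and Hist2h2ac, which have near-identical copies, and the complement gene C6. Ribosome biogenesis (6 of 98 among lower genes, adjusted p = 0.831) did not pass, although the nucleolar protein Nop56 fell from 135.5 ± 2.1 to 74.4 ± 10.1 FPKM (n = 3 each; limma adjusted p = 0.0210).

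Cldn11, a tight junction gene of Sertoli cells, was at 481.1 and 573.3 FPKM in the libraries numbered 2 and at 105.1 to 244.4 FPKM in the others.

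The real grouping gave 404 genes and the highest of the other splits of the 6 libraries 0 in limma (17 to 1251 at an unadjusted p under 0.05), so 1 of 10 splits gave as many. For gene lists with a preset correlation, 5 of 10 splits gave at least the real 9, and the highest other gave 14. With 10 splits the share cannot fall under 0.05. Of the 3 other splits that also part all 3 same-numbered pairs, each called 0 genes, in fits without the replicate block. Every other split puts libraries of both groups on each side, so a difference between the groups widens the spread within the sides. Low counts there follow whatever made the groups differ, so they do not tell what did.

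Changes of several fold lay between libraries whose labels differ by a 5 min exposure and give no time of harvest. The authors' scaling is argued against, since the interferon response list kept a median log2 change of -2.215 or lower with equal medians and with quantile normalization. With harvest at 5 min, loss of transcripts would need a half-life of 2.07 min for the median member with no new synthesis (3.58 min from the lowest untreated to the highest ET-1 library), and new transcription would have to reach across 89 of 183 higher genes that span over 20 kb (48.6%, against 53.2% of genes not called), the distance covered at an assumed 4 kb per min. Neither can be decided here, because the tables hold no half-lives or elongation rates, and a later harvest would relax both. A candidate explanation that also stays open is that the cultures differed before ET-1 was added, which the design cannot separate from the exposure, and the response to ET-1 itself stays open as the biological one.

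The median of macrophage markers was above 0 and that of endothelial markers below 0, although 1 of 15 and 4 of 7 members passed over all genes and both lists had an adjusted p of 0.878 with an estimated correlation. With the other cell types in unchanged proportions, a lower share of the main cell type would raise both. The endothelial median of -1.33 (at most -1.17 with any library left out) argues against that case only. A lower share of the main cell type together with fewer endothelial cells stays open. A higher share of macrophages in the ET-1 libraries may account for the macrophage genes, as 14 of 15 markers were higher, with a median of at least 0.71 with any library left out, and the abundant ones were higher except Cd14 (Lyz2 42.7 and 199.6 FPKM, Cd68 35.4 and 81.2, Tyrobp 14.7 and 64.7). Cd14 was lower (23.0 and 16.6 FPKM), 15 of the 16 listed markers passed the filter on low values, and none stands in another list. Whether ET-1 changed these genes within 1 cell type was not tested.

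Untreated libraries 1 and 3 lay far closer to each other than any other pair. Averaging them as 1 library left 0 calls in limma (1766 genes at an unadjusted p under 0.05), whereas averaging any other pair within a group left 93 to 285. That 1 library was deposited as both is argued against by a mean chi-square per gene of 3.53, where sampling noise alone gives 1 and the other pairs within a group gave 19.9 to 31.9. Library 3 lay between libraries 1 and 2 in 92.7% of the 2026 genes in which these differed by over 0.5 log2 units, against 60% to 63.4% in the ET-1 group, and its best mixture held 20.9% of library 2, with a mean chi-square of 1.72. Cells, RNA or reads of cultures 1 and 2 mixed in library 3 may be behind this, and so may cultures that differ along 1 axis of cell types, which cannot be told apart without duplicate library preparations.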
